A study of Homo sapiens with 6 samples.

How the data were processed

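RNA attached to HA-tagged AEG-1 was measured in 6 libraries of the AEG-1-14 cell line. Per the labels' protocols, cells were lysed after UV treatment, RNA was partly digested with RNase I, complexes were precipitated with an anti-HA antibody, run on a gel and blotted to nitrocellulose, and RNA was released with proteinase K. Libraries were made with a small RNA kit and sequenced as 50 nt single reads on an Illumina HiSeq, per the labels' protocols. Bowtie is named in the submitters' processing notes, without a version. The reference it was run against, the site caller, its threshold, the use of the controls and any handling of repeated reads or crosslink-induced base changes are not given in the sources used here. PAR-CLIP commonly uses a photoreactive nucleoside, which the labels do not name.

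Each deposited file lists the sites of 1 library with a RefSeq mRNA accession, a gene symbol, a start, an end and a score, without a header. Sites were called per library as far as the files show, since their boundaries differ between libraries. The authors' deposited score is on a log2 scale, as read from its values; its normalization is not given in the sources used here. The scores have a regular structure. In 4103 transcripts with at least 6 sites, 2 to the power of the score was, for 61811 of 61811 sites and within a relative tolerance of 2e-05, a whole number times 1 of 5 multipliers (from 0.943 to 1) divided by 1 constant per transcript shared by all libraries. After a random shift of each score, 12.5% of sites met this. A score is therefore an amount relative to a constant of the transcript and was not scaled by library, and scores of different genes are not on one scale of amount. The whole numbers, called units here, sum to 126 and 206 in the HITS-CLIP controls, 55325 and 51308 in HITS-CLIP AEG1, 281 in the PAR-CLIP control and 290801 in PAR-CLIP AEG1. These sums cover the sites of the 4103 transcripts alone, which number 46, 66, 5951, 5263, 118 and 50367 in the same order. Covered nt at all sites, a larger set, were 2390, 3090, 393995, 353474, 8551 and 5733829. What 1 unit stands for was not established, so units were not treated as reads and no count model was run.

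Positions are those of the transcripts in the files, with starts taken as 0-based and printed 1-based. No genome coordinates are given, and coding sequence and UTR boundaries were not analysed here, so the planned division of sites by transcript region was not made. The files list mRNAs alone, so the fixed lists of mitochondrially encoded transcripts and abundant noncoding RNAs had 0 members with a site. Gene symbols were updated from a RefSeq gene table (GRCh38.p14), used for names and for the set of 20056 protein-coding genes. Of 8204 transcripts, 8146 matched by accession, 30 by symbol and 20 by a synonym, and 8 kept the symbol of the file. Blank lines were skipped.

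The lists of genes, the groups, the tests and the first set of alternatives were fixed before the data were examined. Of 19 lists, 7 held mRNAs of secretory, membrane and organelle proteins of the endomembrane system (303 genes) and 7 held mRNAs of cytosolic and nuclear proteins (304 genes). The others covered nuclear-encoded mitochondrial proteins, mitochondrially encoded transcripts, noncoding RNAs, markers of other cell types and MTDH. The genes named are, by rule, the 20 with most PAR-CLIP AEG1 sites, the 10 with the highest minimum over the HITS-CLIP AEG1 replicates, 10 with most sites in the controls, the 3 members of each list with most PAR-CLIP sites, and MTDH, with ties broken by score. Some genes picked by this rule are not reported here.

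A gene counted as present in HITS-CLIP AEG1 when both replicates had a site. Sites were compared by overlap of at least 1 nt, with 100 random placements of each site between the first base of its transcript and the furthest site end there in any library. Pools and lists were compared with Fisher's exact test, two-sided, and the overlap of gene sets with its one-sided form. Odds ratios carry Woolf 95% intervals, with 0.5 added to each cell where a cell was 0. The 16 lists were each set against all others, with Benjamini-Hochberg adjustment at 0.05 for each method. Medians were compared by two-sided permutation of ranks (100000 permutations), and differences of medians in the closing section carry bootstrap intervals (10000 resamples). Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Genes are not independent replicates, so tests over genes describe these libraries.

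The planned count model of HITS-CLIP AEG1 against its control per gene was not run, because no read counts were at hand. Alternatives covered stricter overlap, sites above the median score, at least 2 sites per gene, other gene sets, single replicates and pools without 1 list or without genes seen in controls. Filters on short sites, rankings of PAR-CLIP genes in the pool comparison and logistic models were added later. The calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.

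Site overlap, the pool odds ratio, the whole-number structure, the bootstrap interval and the rank permutation test were tested on simulated data; the logistic models, the overlap of gene sets, the permutation of pool labels and the correlations were not. For the overlap of sites, a set share of 60% of 2000 sites was found as 60%. For the list pools (607 genes), a set odds ratio of 4.33 was found with a median of 4.38 and the interval covered it in 94% of draws; without an effect, 3% of draws passed 0.05. The whole numbers behind simulated scores were found for 100% of 5156 sites. The permutation test of ranks over 500 simulated genes passed 0.05 in 7.5% of draws without a difference.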

Results

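AEG-1, the product of the MTDH gene, is a membrane protein of the endoplasmic reticulum, and the series asked which RNAs it contacts in cells. The cell line, AEG-1-14, derives from HepG3, which the labels call a hepatoblastoma line, and stably expresses AEG-1 with an HA tag at its C-terminus. Cells were irradiated with UV light at 254 nm for HITS-CLIP or at 365 nm for PAR-CLIP, methods in which the light bonds RNA to protein before the protein is precipitated and the attached RNA fragments are sequenced. Negative controls went through the same anti-HA precipitation without UV. The 6 libraries fall into 4 groups, with 2 HITS-CLIP AEG1 libraries, 2 HITS-CLIP negative controls, 1 PAR-CLIP AEG1 library and 1 PAR-CLIP negative control. Each was available as a list of called sites on RefSeq mRNAs, with a log2 score per site by the authors and no read counts, so the read depth is unknown. Nothing in the labels says whether the HITS-CLIP replicates came from separate cultures, so their spread may be technical.

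AEG1 precipitation after UV recovered sites on a large set of mRNAs, whereas the unirradiated controls held few sites, most of all on the mRNA of a plasma protein. HITS-CLIP AEG1 replicate 1 held 6378 sites in 1860 genes and replicate 2 held 5651 sites in 1701 genes. The HITS-CLIP negative controls held 60 sites in 49 genes and 90 sites in 78 genes. PAR-CLIP AEG1 held 60085 sites in 8002 genes, and its control held 121 sites in 66 genes. ALB, the mRNA of serum albumin, led all 3 controls, with 11, 9 and 13 sites, against 5 and 10 sites in the HITS-CLIP AEG1 libraries and 3 in PAR-CLIP AEG1. The highest ALB score was 0.36, 0.36 and -0.57 in the controls and 6.31, 5.34 and 5.22 in the AEG1 libraries, where single sites were wide, such as nt 344 to 1928 in HITS-CLIP replicate 1.

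The HITS-CLIP AEG1 libraries averaged 6014.5 ± 514 sites (SD, n = 2) and the controls 75 ± 21.2 (SD, n = 2), a ratio of 80.2; the smallest p that an exact permutation test of 2 against 2 libraries allows is 0.333. The PAR-CLIP ratio was 497, from 1 library on each side and therefore without a replicate check. By genes, the HITS-CLIP averages were 1780.5 ± 112 and 63.5 ± 20.5. Without sites of 25 nt or less, the HITS-CLIP ratio was 224, because 65% and 67.8% of the control sites were that short against 6.8% and 7.01% of the AEG1 sites. Among sites above the median score, the PAR-CLIP ratio was 2149.

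Besides ALB, the genes with a site in all 3 controls included ABCC3, an organic anion exporter, DKK1, a secreted Wnt antagonist, GC, the vitamin D binding protein, and SERPINA1, or alpha-1-antitrypsin. C3, the central complement component, had 10 sites in the PAR-CLIP control and 4 in PAR-CLIP AEG1, with highest scores of -0.04 and 8.05, and 24 and 21 in HITS-CLIP AEG1. EEF1A1, a translation elongation factor, had 8 sites in the PAR-CLIP control and 4 in PAR-CLIP AEG1, with highest scores of -1.15 and 5.20, and 12 in each HITS-CLIP AEG1 library. FTL, the ferritin light chain, had 3 in the PAR-CLIP control and 1 in PAR-CLIP AEG1, with highest scores of 2.09 and 7.82, and PLCG2, a phospholipase, had 2 in the second HITS-CLIP control and 2 in the PAR-CLIP control. Of the 94 protein-coding genes seen in either HITS-CLIP control, 69 also had sites in both HITS-CLIP AEG1 libraries.

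**Figure D1:**
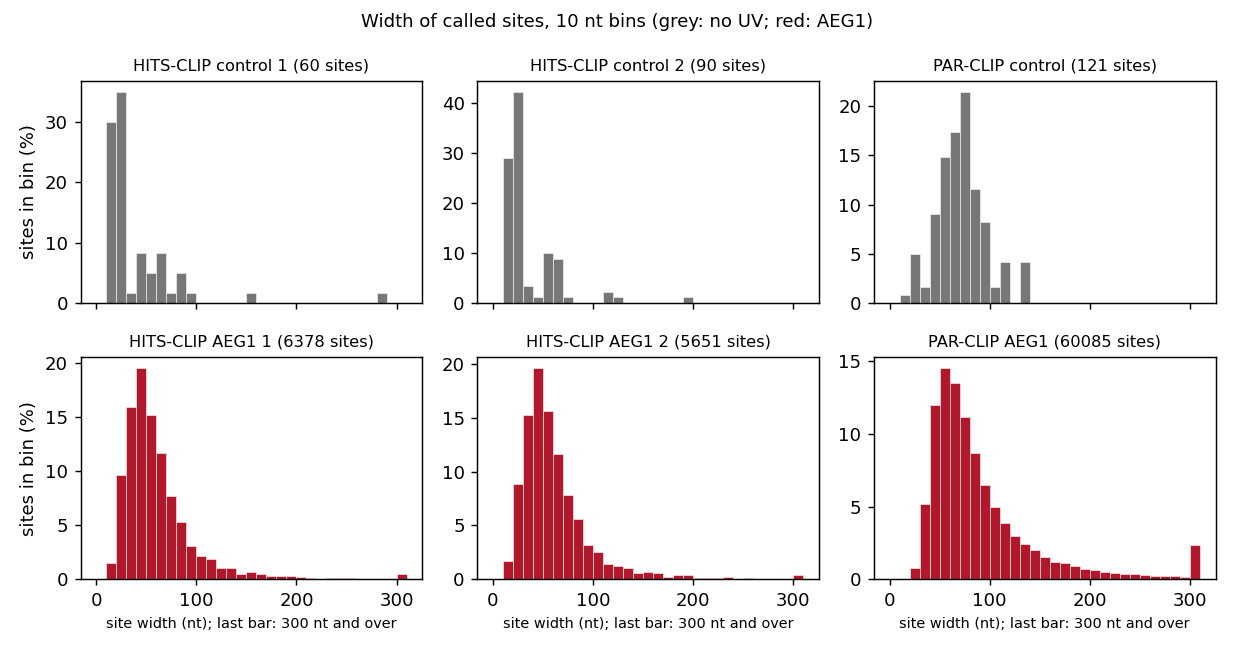
Width of called sites in nt (x axis, 10 nt bins, the last bar holding sites of 300 nt and over) as a percentage of the sites of each library (y axis, each panel on its own scale), with unirradiated controls in grey and AEG1 libraries in red. The HITS-CLIP controls peak at short sites, with a median of 21 nt in each, against 51 and 52 nt in HITS-CLIP AEG1, 71 nt in the PAR-CLIP control and 73 nt in PAR-CLIP AEG1.

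The HITS-CLIP replicates placed sites on largely the same mRNAs, with long mRNAs of secreted and membrane proteins at the top of both. APOB, the core protein of VLDL and LDL, held 98 and 97 sites. FN1, or fibronectin, held 55 and 58, IGF2R, the receptor that carries mannose-phosphate-tagged enzymes to lysosomes, 52 and 46, and A2M, a plasma protease inhibitor, 39 and 37. The matrix proteins AGRN and LAMC1 held 49 and 35 sites and 31 and 32 sites, and PLXNB2, a semaphorin receptor, 31 and 28. SPTBN1, a spectrin of the membrane skeleton, was the exception among the leading 10 as a cytosolic protein, with 30 and 42 sites. NOMO1 and NOMO3, near-identical copies of an ER membrane protein gene, held 33 and 28 sites and 31 and 28 sites, and are uncertain because fragments may belong to either copy.

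Of the replicate 1 sites, 63.2% (exact 95% binomial interval 62.0 to 64.4, counting error only) overlapped a replicate 2 site by at least 1 nt, against 32.2% ± 0.463 for 100 random placements (SD) of each site on its own transcript. The share of replicate 2 sites in replicate 1 was 71.3%, against 35.9% ± 0.529 by random placement. Random placement was even up to the furthest site end in any library. HITS-CLIP sites were not spread evenly, with a median position of 0.414 of the furthest PAR-CLIP position over 463 transcripts. The random shares may therefore be too low, and the excess over them cannot be read wholly as repeated sites. When the overlap had to cover 50% or more of each site, the replicate 1 share was 49.2%. A total of 1320 genes had sites in both replicates and 2241 in either. Over these 1320 genes, which are not independent replicates, Spearman's rho between the replicates was 0.843 for the number of sites and 0.944 for the highest score.

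Most genes with HITS-CLIP sites also had PAR-CLIP sites, but by number of sites, the only measure used for this ranking, the leading genes of the methods differed. Of 1318 protein-coding genes in both HITS-CLIP replicates, 1243 (94.3%) had a PAR-CLIP site, where independent lists would share 524. The odds ratio over the 20056 protein-coding genes of the reference table was 29.6 (95% interval 23.4 to 37.4; one-sided Fisher's exact test, p too small to be represented). Many of these 20056 genes will not be transcribed in this line, which raises any such ratio. Among members of the fixed gene lists, all 339 genes with HITS-CLIP sites had PAR-CLIP sites, against 315 expected, but 633 of 682 members had PAR-CLIP sites and genes without transcripts raise this ratio too. With PAR-CLIP restricted to as many top genes by number of sites, 423 of the HITS-CLIP genes (32.1%) were shared, an odds ratio of 9.4.

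Several genes with the highest numbers of PAR-CLIP sites encode very large proteins. By the same measure, 106 of 303 endomembrane and 97 of 304 cytosol and nucleus list members were among the 1320 leading genes (odds ratio 1.15, two-sided Fisher's exact test, p = 0.440). UBR4 and HUWE1, both ubiquitin ligases, held 90 and 86 sites, DYNC1H1, the dynein heavy chain, 88, DST and MACF1, cytoskeletal linkers, 83 and 65, and PRKDC, the DNA-dependent protein kinase, 72. In HITS-CLIP, UBR4 held 1 site in each replicate, HUWE1 1 and 0, DST 0 and 1, and MACF1, TRRAP, CNOT1 and NBPF10 none. DYNC1H1 held 12 and 11. The membrane and secreted proteins among the leading 20, RELN with 70 PAR-CLIP sites, FAT1 with 66, LRP1 with 56 and the transporter SLC16A7 with 60, held 30 and 25, 12 and 14, 28 and 22, and 4 and 0 HITS-CLIP sites. The other members, with 52 to 68 PAR-CLIP sites, were CDK6, MKI67, CBX5, SMG1, ARHGAP35, KMT2D and PRRC2C, and each held at most 4 sites in either HITS-CLIP library. On MKI67 the HITS-CLIP controls held 1 site each (scores 5.45 and 4.45), against highest scores of 6.04 and 5.45 in HITS-CLIP AEG1. NBPF10 belongs to a family of near-identical copies and is uncertain.

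The number of PAR-CLIP sites per gene rose with the furthest position covered (Spearman's rho 0.594 across 8002 genes). That position comes from the same sites that are counted, so part of the rise was built in. The number of sites is a poor measure of amount on mRNAs where single sites span most of the transcript. ALB had 3 PAR-CLIP sites, the highest-scoring from nt 29 to 2107 of its mRNA. On A2M, with 5 PAR-CLIP sites, the highest-scoring ran from nt 1258 to 3739. APOB had 23 PAR-CLIP sites, fewer than in either HITS-CLIP library.

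In HITS-CLIP, mRNAs of proteins made at the endoplasmic reticulum carried sites more often than mRNAs of cytosolic and nuclear proteins. Of 303 members of the 7 endomembrane lists, 222 (73.3%) had a site in both replicates, against 102 of 304 members (33.6%) of the 7 cytosol and nucleus lists. The odds ratio was 5.43 (95% interval 3.83 to 7.69; two-sided Fisher's exact test, p = 4.46e-23). Genes with sites also held more of them, with a median of 6 in each replicate for endomembrane genes and 2 for the others. These numbers were not divided by transcript length, and among list genes with PAR-CLIP sites the median furthest PAR-CLIP position was 2667.5 against 2058 nt. The median highest HITS-CLIP score of endomembrane genes was 7.43 against 3.76 in replicate 1 and 7.45 against 3.74 in replicate 2. Permutation tests gave an adjusted p of 1.2e-05 for each, resting on p = 1e-05, the smallest the permutations can give.

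Lysosomal proteins stood highest, with 32 of 36 members (odds ratio against all other lists 8.86, exact test, Benjamini-Hochberg adjusted p = 4.04e-06 over 16 lists, as for the following lists). The peptidase TPP1 held 11 and 7 sites and the glucosidase GAA 8 and 8. ER folding and quality control followed with 32 of 40 (odds ratio 4.38, exact adjusted p = 0.000188), where the folding sensor UGGT1 held 15 and 11 sites and SEL1L, an adaptor of ER-associated degradation, 10 and 8, while the co-chaperone DNAJC3 held 1 and 1. Plasma membrane transporters and receptors had 45 of 58 members (3.90, exact adjusted p = 3.89e-05), with INSR, the insulin receptor, at 7 and 7. The translocation and glycosylation machinery had 32 of 43 (3.16, exact adjusted p = 0.00145), with SSR1 of the translocon at 7 and 7, EMC1 at 5 and 4, and the cargo receptor TMED10 at 3 and 4. Secreted liver proteins had 30 of 42 (2.69, exact adjusted p = 0.00623), with CP, or ceruloplasmin, at 21 and 17 and coagulation factor F5 at 2 and 1.

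The remaining pair of endomembrane lists did not pass. Golgi and vesicle transport membrane proteins had 26 of 40 (odds ratio 1.96, exact adjusted p = 0.0626), with GLG1 at 17 and 11 sites, TGOLN2 at 8 and 7 and SORT1 at 7 and 5. ER lipid and sterol enzymes had 25 of 44 (1.36, exact adjusted p = 0.352), where the sterol-regulated transcription factors SREBF1 and SREBF2, made as ER membrane proteins, held 8 and 8 and 5 and 5 sites, and the desaturase FADS1 2 and 1.

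Chromatin and nuclear factors stood lowest, with 4 of 45 members (odds ratio 0.0882, exact adjusted p = 5.43e-08); CBX5 held 1 and 0 sites, at a score of 5.31 that its site in each HITS-CLIP control matched or exceeded (5.39 and 5.31), KMT2D 0 and 1, and KMT2A 1 and 1. The proteasome, chaperonin and cytosolic chaperone list had 9 of 44 (0.241, exact adjusted p = 0.000188), with UBA1 at 1 and 1 and no HITS-CLIP site on PSMD1 or HSPH1. Translation factors and tRNA synthetases had 10 of 44 (0.277, exact adjusted p = 0.000506), with EIF4G1 at 7 and 5, EIF3A at 1 and 0 and none on EPRS1. Nuclear RNA-binding proteins had 14 of 45 (0.435, exact adjusted p = 0.0188), with SRRM2 at 8 and 3 and SNRNP200 at 1 and 0. Glycolysis and cytosolic metabolism had 13 of 40 (0.468, exact adjusted p = 0.0442), with FASN, the fatty acid synthase, at 16 and 13, ACLY at 1 and 0 and none on ACACA. Nuclear-encoded mitochondrial proteins, outside both pools, had 12 of 52 (0.279, exact adjusted p = 0.000188), with OGDH at 1 and 0 and none on NDUFS1 or CS.

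Cytosolic ribosomal proteins, with 29 of 46 (odds ratio 1.80, exact adjusted p = 0.0769), and the cytoskeleton list, with 23 of 40 (1.40, exact adjusted p = 0.352), did not pass. RPL4 held 1 and 1 sites, RPL15 2 and 0, RPL13 0 and 2, FLNA 5 and 7, SPTAN1 19 and 10, and TLN1 none. Markers of blood, endothelial and connective tissue cells had sites in 2 of 22 (0.0961, exact adjusted p = 0.000221): the macrophage-associated CD68 at 3 and 3 and LYZ, or lysozyme, at 8 and 6; CD14 held 1 and 0.

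**Figure D2:**
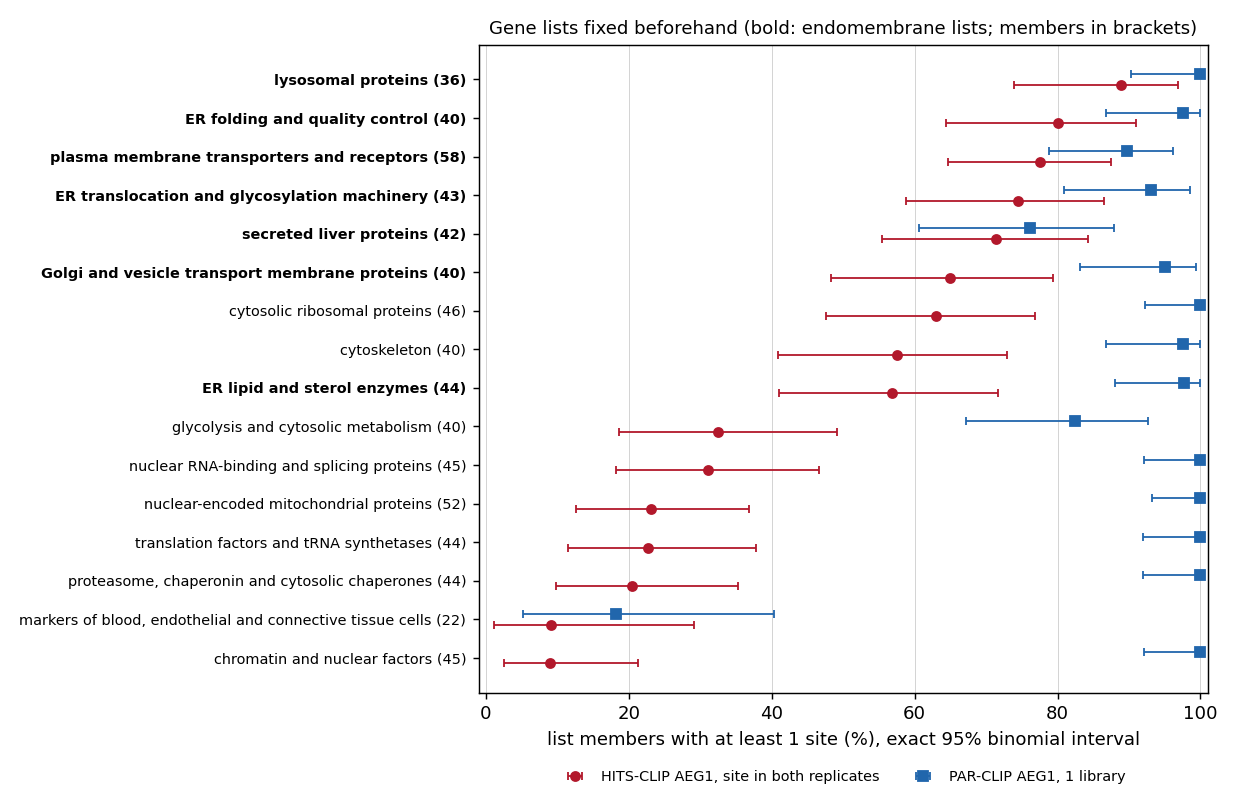
Percentage of the members of each gene list with at least 1 called site (x axis), for HITS-CLIP AEG1 (red circles, site in both replicates) and PAR-CLIP AEG1 (blue squares, 1 library), with exact 95% binomial intervals for counting error; list names are on the y axis, endomembrane lists in bold, with member numbers in brackets. HITS-CLIP runs from 8.89% for chromatin and nuclear factors to 88.9% for lysosomal proteins, while all PAR-CLIP lists but 2, the secreted liver proteins at 76.2% and the markers of other cell types at 18.2%, lie at 82.5% or above.

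In PAR-CLIP nearly all list members had a site, and the endomembrane pool was slightly behind. Sites were present on 280 of 303 endomembrane genes (92.4%) and 296 of 304 cytosol and nucleus genes (97.4%), an odds ratio of 0.329 (95% interval 0.145 to 0.748; two-sided Fisher's exact test, p = 0.00563). Secreted liver proteins were lower than the other lists, with 32 of 42 (odds ratio 0.208, exact adjusted p = 0.00301), as were the markers of other cell types with 4 of 22 (0.011, exact adjusted p = 9.13e-18). The 10 secreted proteins without a PAR-CLIP site, among them SERPINC1 (antithrombin), PLG (plasminogen) and HPX (hemopexin), named after their values were seen, had no HITS-CLIP site in either replicate. The same held for every member of the other lists that lacked a PAR-CLIP site. The PAR-CLIP pool odds ratio therefore rests on genes absent from every AEG1 library. None of the other 14 lists passed, and 7 of the 16 had a site on every member. Without the secreted proteins the pool odds ratio was 0.516 (Fisher's exact test, p = 0.181), and with at least 2 sites per gene it was 0.552 (p = 0.0541).

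Covered length, summed units and scores ran the other way in the same PAR-CLIP library. With at least 1 site above the median score required, the odds ratio was 2.85 (95% interval 2.01 to 4.03). Among genes with sites, the median highest score was 9.15 for endomembrane genes, 2.16 above that of cytosol and nucleus genes (permutation test, adjusted p = 1.2e-05), and the median covered length was 1729 nt against 1308.5 nt (permutation test, p = 0.00031). Covered length was not divided by transcript length. The furthest PAR-CLIP position of the same genes also differed, with medians of 2667.5 and 2058 nt, so covered length alone cannot be read as an amount. Summed units per gene had medians of 136 and 86 (permutation test, p = 1e-05, the smallest the permutations can give). Units were not divided by transcript length either, and what 1 unit stands for is unknown. The number of sites per gene, 10.5 against 9, did not pass (permutation test, adjusted p = 0.0996). Each score is relative to a constant of its transcript, so comparisons of scores between genes, in HITS-CLIP too, include those constants. The lowest PAR-CLIP score per gene, which follows the constant, already had a median of 4.62 in endomembrane and 3.12 in cytosol and nucleus genes. Members with many PAR-CLIP sites occurred in both pools, such as INSR with 50, F5 with 43, UGGT1 with 37, SSR1 with 33 and TGOLN2 with 32, and FLNA with 51, SPTAN1 with 48, TLN1 with 44, SRRM2 and SNRNP200 with 42 each, KMT2A with 38 and ACACA with 37.

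The pools showed no difference that passed in the unirradiated controls, where few members had sites. The odds ratio was 2.37 in each HITS-CLIP control (7 of 303 against 3 of 304; 95% interval 0.608 to 9.26; Fisher's exact test, p = 0.222) and 1.51 in the PAR-CLIP control (22 against 15 genes; 0.767 to 2.97; p = 0.241). These intervals are wide and include the HITS-CLIP AEG1 value of 5.43 in the HITS-CLIP controls.

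The mRNA of the precipitated protein itself, MTDH (NM_178812), held 10 and 8 sites in HITS-CLIP AEG1, none in the HITS-CLIP controls, 1 in the PAR-CLIP control and 12 in PAR-CLIP AEG1. The HITS-CLIP sites lay between nt 396 and 1941 of the transcript, with the highest score at nt 942 to 989 in replicate 1 (9.24) and from nt 942 in replicate 2 (10.12). The single control site lay within the same stretch, at nt 885 to 991. PAR-CLIP sites ran from nt 258 to 4449, with the highest score of 12.34 on a single site from nt 833 to 2107. The cells carry an AEG-1 transgene, and sites on its RNA and on the endogenous mRNA cannot be separated here.

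**Figure D3:**
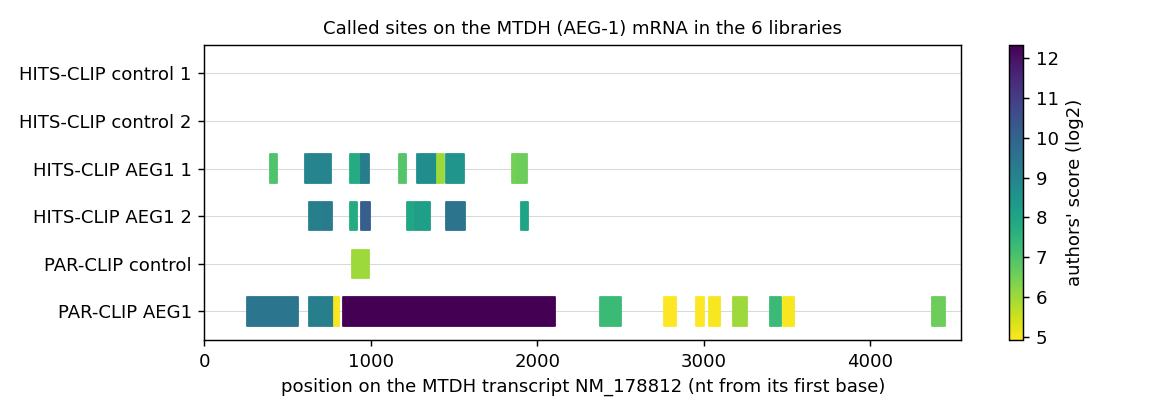
Called sites on the MTDH mRNA (NM_178812) in the 6 libraries, with the position in nt from the first base of the transcript on the x axis, 1 line per library on the y axis and the colour giving the authors' log2 score. HITS-CLIP AEG1 sites lie between nt 396 and 1941 in both replicates, the PAR-CLIP control has 1 site, and PAR-CLIP AEG1 sites reach nt 4449.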

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

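The test of near-complete detection was chosen after the higher PAR-CLIP scores of endomembrane genes had been seen, and its rankings by covered length and summed units and the ratios for all rankings were added after that; the abundance and length tests were written before they were run, although medians of both stand-ins per list had been looked at.

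The contrast between endomembrane and cytosol and nucleus genes differed between the crosslinking methods, with an odds ratio 16.5 times as high in HITS-CLIP as in PAR-CLIP, where detection was nearly complete. Permutation of the pool labels over genes gave p = 0.0001, the smallest that 10000 permutations can give. That permutation takes the pools as unrelated to both methods, so the HITS-CLIP excess alone can give a small p. It does not test whether the odds ratios of the methods are equal. The PAR-CLIP odds ratio in the factor of 16.5 rests on the few list members without a PAR-CLIP site, none of which had a HITS-CLIP site either. Among genes with PAR-CLIP sites, the HITS-CLIP odds ratio was 7.28 before and 10.4 (95% interval 6.77 to 15.9) after adjustment for each gene's lowest PAR-CLIP score, a stand-in for abundance in which a lower score went with more HITS-CLIP detection (odds ratio 0.825 per log2 unit), which argues against abundance as far as the stand-in holds; no RNA measurement was at hand to check it. Adjusted for the furthest PAR-CLIP position, a stand-in for length, it was 7.49 (5.11 to 11.0), which argues against length as far as this stand-in holds. The stand-in depends on which sites were called and was itself little related to HITS-CLIP detection (odds ratio 0.924 per log2 unit, 0.774 to 1.10). No transcript lengths were at hand to check it. Near-complete detection in PAR-CLIP stays open. With PAR-CLIP limited to its 1320 top genes, the odds ratio was 8.14 (4.58 to 14.5) by highest score, which includes the transcript constants. It was 1.46 (1.06 to 2.02) by covered length, which was not divided by transcript length. By summed units it was 1.41 (1.01 to 1.97), which did not pass Fisher's exact test (p = 0.0507), and by number of sites 1.15 (0.819 to 1.61). The PAR-CLIP excess may thus be partly hidden by depth. The HITS-CLIP odds ratio remained 3.71, 3.85 and 4.73 times as high by covered length, units and sites (permutation p = 0.0001 each, the smallest possible) but 0.667 times by highest score (permutation p = 0.0920). These permutations have the limit given above for the factor of 16.5. A difference between the crosslinking chemistries in which RNAs they capture is a further candidate explanation and was not tested, because each method has its own libraries and PAR-CLIP has 1.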

How the results depend on the processing

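Alternatives that filtered sites of 25 nt or less, ranked PAR-CLIP genes in the pool comparison, used a logistic model or left out a library from the yield, and all those of the PAR-CLIP yield, were chosen after seeing the data; list members as background were named in the design. The HITS-CLIP excess of endomembrane genes kept its direction and passed the test under all 10 alternatives run, with odds ratios from 3.32 to 32.1 (3.94 to 4.44 with a single replicate). The 32.1 comes from sites above the median score, a filter that includes the transcript constants, and the next highest value was 10.5. The overlap of HITS-CLIP and PAR-CLIP genes also kept its direction and passed under all 7, from 9.4 to 114 (22.9 to 23.8 with a single replicate). The 114 comes from list members as background, with a 0 cell and a 95% interval of 7.01 to 1858. The PAR-CLIP pool odds ratio of 0.329 turned to 2.85 among sites above the median score and, among as many top genes, to 1.15 by number of sites, 8.14 by highest score, 1.46 by covered length and 1.41 by summed units; it lost its call at 0.552 with at least 2 sites per gene and at 0.516 without the secreted liver proteins, which hold 10 of the 23 endomembrane genes without a site. The site overlap moved from 63.2% to 49.2% when 50% of each site was required, 55.9% above the median score and 71.3% as the share of replicate 2, whose list is shorter. The HITS-CLIP yield ratio moved to 224 without short sites and ranged from 66.8 to 100.2 with 1 library left out; the PAR-CLIP ratio moved to 2149 above the median score. Where no cause is given, the cause was not tested. Leaving out ribosomal, transfer, small nuclear and mitochondrial RNAs removed nothing, and the alternatives on summed reads, transcript regions and the per-gene count model were not run. No paired analysis was possible because the labels share replicate numbers without stating pairs, the yield rests on no test, and the per-gene model that would have held a replicate block was not run. Read depth is unknown, so a gene without a site in HITS-CLIP may be one that fell below the caller's threshold, as the rise of the HITS-CLIP odds ratio from 3.32 (either replicate) to 7.90 (at least 2 sites per gene) allows.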

Other observations

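The gene families, the comparison that joins depth and wide sites and the division of transcripts by whether site numbers can be matched were chosen after seeing the data; the test of wide sites was added once wide sites and the position shift had been seen, before its own result.

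Gene families, formed from the letters before the first digit of the symbol with at least 10 members among 8050 protein-coding genes with sites, gave 8 of 88 tested with an excess of HITS-CLIP genes and none with a deficit (Fisher's exact test, Benjamini-Hochberg adjusted p under the 0.05 limit), against 16.4% of all these genes. Solute carriers (SLC) had 58 of 174 members (odds ratio 2.63, exact adjusted p = 2.86e-06), the p24 cargo receptors (TMED) 8 of 11 (13.7, exact adjusted p = 0.000962), the tetraspanins (TSPAN) 7 of 13 (5.99, exact adjusted p = 0.0235) and the CD family 10 of 17 (7.34, exact adjusted p = 0.00126). The RPS family, which includes S6 kinases beside ribosomal proteins, had 21 of 40 (5.72, exact adjusted p = 6.64e-06) and the RPL family 20 of 50 (3.44, exact adjusted p = 0.000962), whereas the fixed list of cytosolic ribosomal proteins did not pass against the other lists (29 of 46, exact adjusted p = 0.0769). The ATP (20 of 58) and TM (8 of 11) families also passed. The larger TMEM family, separate from TM by this rule, did not (26 of 113, exact adjusted p = 0.275). No member was present among 29 DDX helicase, 27 MRPS mitochondrial ribosomal and 27 RBM RNA-binding genes, although none of these passed after adjustment (DDX, exact adjusted p = 0.0865). A family of 29 members or fewer could therefore hardly pass with a deficit.

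PAR-CLIP sites lay further toward the 3' end than HITS-CLIP sites of the same transcript. Over 463 transcripts with at least 3 sites in each AEG1 library, the median position, as a fraction of the furthest PAR-CLIP position, was 0.414 in HITS-CLIP and 0.546 in PAR-CLIP, and the median difference was 0.151 (95% interval 0.128 to 0.174; higher in 345 of 463). In 330 transcripts with more PAR-CLIP sites than the mean of the HITS-CLIP replicates, keeping as many top-scoring PAR-CLIP sites as that mean lowered it from 0.151 (0.120 to 0.181) to 0.0511 (0.0398 to 0.0707); in the other 133, at 0.151 (0.0861 to 0.198), numbers could not be matched and depth stays open. With each site weighted by its length, so that wide PAR-CLIP sites count by nucleotides, the difference was 0.0874 (0.074 to 0.0959) over all 463, and with both changes 0.0483 (0.0269 to 0.0598) over the 330. Depth and wide sites may thus account for part of the shift, and these values argue against wide sites as its whole cause and, in the 330 transcripts, against depth as its whole cause. A difference in where the crosslinks form remains as an untested hypothesis, since coding and untranslated regions were not analysed here.

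Short sites made up most of the HITS-CLIP control lists. Where a control site of 25 nt or less overlapped a HITS-CLIP AEG1 site, the AEG1 score was higher by a median of 0.58 (95% interval 0.08 to 0.67, 155 pairs), against 6.12 (5.53 to 6.55, 96 pairs) at wider control sites. The pairs set 39 and 61 short control sites against 2 AEG1 libraries, and 27 of these sites overlapped between the controls. The same locus can thus enter more than once, and the intervals are too narrow. Control sites without an AEG1 site did not enter. At the shared loci, such fragments may be a background of similar amount in the HITS-CLIP libraries. In both HITS-CLIP AEG1 libraries, 150 genes had short sites alone, of which 0 were endomembrane and 3 cytosol and nucleus list members.

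The lowest scores in the files belonged to ALB, EEF1A1, ENO1, AHSG and APOA1, with minima of -3.89, -3.56, -3.49, -2.87 and -2.77. GC, also a plasma protein, held the highest scores of HITS-CLIP AEG1, at 20.28 and 20.55, on NM_001204306, and 20.23 in PAR-CLIP AEG1. It also held the highest scores of the HITS-CLIP controls, 12.58 and 14.75, and of the PAR-CLIP control, 13.16. Scores of different genes include the transcript constants, so these ranks are not ranks of amount. PLCG2 had 1 site in each AEG1 library, at nt 7942 to 8179 in HITS-CLIP and 7940 to 8181 in PAR-CLIP, with scores of 16.92, 17.20 and 15.69. Its highest scores were 12.60 in the second HITS-CLIP control and 12.18 in the PAR-CLIP control.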
